A study of Mus musculus with 9 samples.

How the data were processed

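Gene expression was measured in 9 samples of lung epithelial cells from adult mice, sorted by flow cytometry as EpCAM-positive, CD45-negative and CD31-negative cells. Per the labels, 3 samples came from lung squamous tumours of mice lacking Lkb1 and Pten (LP tumours), 3 from lung adenocarcinomas of mice with the oncogenic Kras G12D allele (Kras tumours) and 3 from the lungs of wild-type mice (normal). The titles call the 3 samples of each group biological replicates, and how many animals gave each sample is not given in the sources used here. The p-values therefore measure the spread between these samples.

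Biotin-labelled cRNA was hybridised to single-colour Affymetrix arrays, per the labels' protocols. The deposited values are RMA expression values made with the oligo package in R 3.0.1, per the submitters' processing notes, and RMA comprises background correction, normalization between arrays and summary of probes into probe sets. The log2 scale of the deposited values was read from the values, which ran from 3.18 to 14.15 with nearly equal quartiles in the 9 samples. The settings of RMA and the genome build of the array are not given in the sources used here, and no coordinates are printed. RMA normalization sets the arrays to a common distribution, so a change of total RNA per cell is not visible in these values.

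The deposited table held 34760 probe sets. The platform annotation gave 1 gene symbol for 21640 of them, several for 1321, and did not list the other 11799, which are unnamed here. Symbols were updated by Entrez ID through a RefSeq gene table of the assembly GRCm38.p6, in which 21553 probe sets matched and 87 kept the symbol of the platform annotation. The 954 genes with more than 1 probe set were represented by the probe set with the highest mean over all 9 samples, leaving 19937 genes. Pten, Kras and Ly6a had no probe set with a single gene symbol in the tables used and were not analysed here.

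Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the log2 values of all 9 samples, with 1 coefficient per group, 6 residual degrees of freedom and no block for the replicate number. The spread of a gene was pooled over the 3 groups, so the SE and p of a comparison also carry the spread of the group not compared. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 19937 genes, separately in each of 3 comparisons, and limma's moderated F test compared the 3 groups at once. Gene lists were tested with camera, which asks whether the genes of a list shifted relative to all other genes, at a preset correlation between genes of 0.01, with adjustment over the 38 lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list moved on balance in 1 direction without reference to other genes, were run as alternatives. The lists held 740 entries, of which 690 were measured. The overlap of both tumour comparisons was set against 100 simulations of unchanged groups that shared the same normal samples.

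The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 10 higher and 10 lower genes with the largest change among called genes whose 3 samples of a group all lay beyond the 3 of the other, passing over clone and predicted-gene names. It added up to 4 called members of each list with the largest change, and a set of genes taken whatever their values: Stk11, Cd274, Trp63, Sox2, Krt5, Krt14, Krt6a, Ngfr, Nkx2-1, Sftpc, Scgb1a1, Epcam, Ptprc, Pecam1, Cxcl1, Cxcl5, Cxcl3, Ppbp and Cdkn2a. The alternatives were the mean of the probe sets of a gene, every probe set tested, the 30% of genes with the lowest mean left out, quantile normalization, median centring, a trended and robust prior, sample weights, a replicate block, each sample left out, only the 2 groups compared in the fit and an adjusted p under 0.01. Genes on X and Y left out, and the Kras tumours represented by replicate 3 alone, were added after the data were seen.

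The procedure was tested on simulated data for the comparison of LP tumours with normal samples, over 19937 genes. It recovered 20% of 70 genes changed by 0.5 on the log2 scale, 82.1% of 67 changed by 1 and 100% of 63 changed by 2. Of its 141 calls 6.38% were unchanged genes. Far fewer genes were changed there than were called in the data, and the simulated noise was independent between genes. These rates need not hold for the data. The precision of array values is limited by the number of samples, 3 per group. Figures were drawn with matplotlib 3.10.9.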

Results

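The data comprised 9 expression profiles of sorted lung epithelial cells: 3 from LP tumours, 3 from Kras tumours and 3 from normal lungs. Median log2 values per sample lay between 7.35 and 7.48. Over all genes, the 3 normal samples correlated at 0.994, the LP tumours at 0.978 to 0.993 and the Kras tumours at 0.973 to 0.978, whereas an LP tumour and a normal sample correlated at 0.862 to 0.891. The first principal component held 62.0% of the variance and separated the LP tumours from the other samples, and the second, with 23.3%, separated the Kras tumours from the normal samples. By limma's F test, 8660 of 19937 genes (43.4%) differed among the 3 groups.

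Stk11, the gene that encodes the kinase Lkb1 and that was targeted in the LP mice, was lower in every LP tumour (probe set 10364683). Its log2 values were 9.83, 9.83 and 9.76 in the LP tumours, 11.17, 11.23 and 11.05 in the normal samples and 10.76, 10.49 and 10.76 in the Kras tumours. Stk11 fell 2.54-fold in the LP tumours against normal (log2 difference -1.34 ± 0.10 SE, n = 3 per group, adjusted p = 7.9e-06) and by 0.86 on the log2 scale against the Kras tumours (adjusted p = 0.00021). It also fell 1.40-fold in the Kras tumours against normal (adjusted p = 0.01), a call that was lost with Kras replicate 3 alone (adjusted p = 0.088; lowest over all settings 0.0049). Which part of Stk11 the probe set covers relative to the deletion was not analysed here, so its level is a partial check of the labels.

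**Figure D1:**
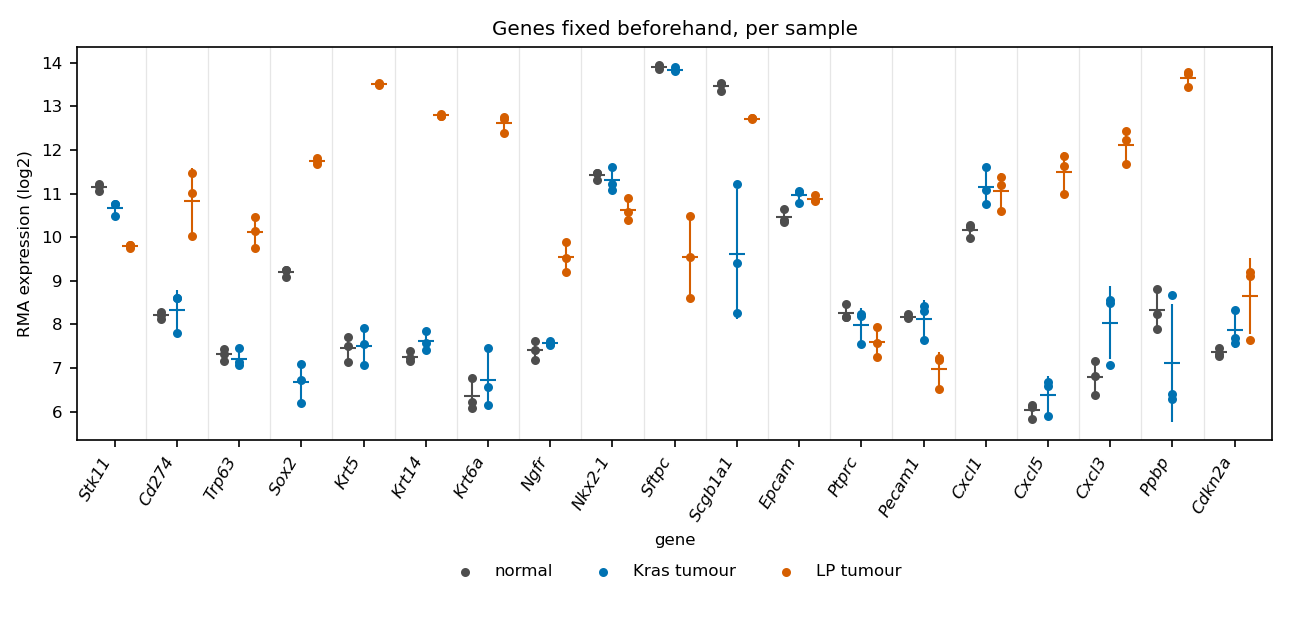
RMA expression (log2, vertical axis) of 19 genes fixed beforehand in each of the 9 samples; points are samples, horizontal ticks are group means and vertical bars are 1 SD (n = 3 per group). Krt5, Krt14 and Krt6a stood at means of 13.51, 12.79 and 12.61 in the LP tumours against 7.46, 7.26 and 6.35 in the normal samples, while Sftpc stood at 13.91 in the normal samples, 13.84 in the Kras tumours and 9.54 in the LP tumours.

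The comparison of LP tumours with normal epithelium asked how the squamous tumours that arise without Lkb1 and Pten differ from the cells of the healthy lung, including in Pdl1, the immune checkpoint ligand encoded by Cd274. Krt6b and Dsg3 rose 110-fold and 107-fold, and the alveolar genes Lamp3 and Sftpa1 fell 139-fold and 41.0-fold. Cd274 rose 6.20-fold, from 8.21 ± 0.07 to 10.84 ± 0.74 (mean ± SD, n = 3), with a log2 difference of 2.63 ± 0.34 (SE, adjusted p = 0.00029). Its values in the 3 LP tumours were 10.03, 11.47 and 11.02. The chemokine gene Cxcl5 and the interferon-induced gene Irf7 also rose, 44.2-fold and 17.8-fold.

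Of the 36 measured keratinisation genes 34 rose and 0 fell (camera adjusted p = 3.5e-21, and adjusted p = 0.083 with an estimated correlation). Counts for lists are adjusted over all genes, and counts adjusted over the list alone were the same unless given. Krt6b rose 110-fold (log2 difference 6.78 ± 0.26 SE), Krt4 88.5-fold (6.47 ± 0.13), Krt13 81.8-fold (6.35 ± 0.18) and Krt6a 76.4-fold (6.26 ± 0.31), with adjusted p at most 5.7e-07 for each of these keratins. Of the 23 basal squamous genes 19 rose and 1 fell (camera adjusted p = 3.1e-12, and adjusted p = 0.23 with an estimated correlation). Dsg3, a desmosomal cadherin, rose 107-fold (6.75 ± 0.10, adjusted p = 2.2e-09), Krt5 66.5-fold and Krt14 46.3-fold. The basal cell transcription factor Trp63 rose 6.97-fold (2.80 ± 0.18, adjusted p = 3.1e-06), Sox2 5.84-fold (2.55 ± 0.19, adjusted p = 9.3e-06) and the receptor Ngfr 4.38-fold (2.13 ± 0.18, adjusted p = 1.6e-05).

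The largest increases outside these lists included the serine protease genes Tmprss11g (157-fold) and Tmprss11b (104-fold), Fads2b (128-fold), Serpinb11 (127-fold), Psca (104-fold) and Akr1c18 (96.3-fold), each with an adjusted p of at most 5.4e-05. Serpinb5, of the keratinisation list, rose 104-fold (log2 difference 6.70 ± 0.15 SE).

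Alveolar type 2 genes fell as a list, with 21 of 25 lower and 0 higher, or 22 lower when adjusted over the list alone (median log2 difference -4.57, camera adjusted p = 1.3e-15, and adjusted p = 0.046 with an estimated correlation). Lamp3, a lamellar body protein gene, fell 139-fold (-7.12 ± 0.22 SE, adjusted p = 4e-08), Hc 82.8-fold, Lyz1 44.6-fold and Egfl6 41.9-fold. The surfactant genes Sftpa1 and Sftpc fell 41.0-fold and 20.6-fold, and the lung lineage factor Nkx2-1 fell 1.74-fold (-0.80 ± 0.16, adjusted p = 0.0041). Lgi3, Enpep, Chia1, Inmt and Lrp2 were also among the largest decreases, from 69-fold to 43.6-fold. Of the 29 ciliated cell genes 27 fell and 0 rose (camera adjusted p = 8.6e-23, and adjusted p = 0.13 with an estimated correlation), among them Rsph4a (21.5-fold) and Ak7 (15.3-fold). Of the 20 alveolar type 1 genes 9 fell and 2 rose, or 10 and 2 when adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.64 with an estimated correlation). Cldn18 was 40.2-fold and Ager 17.4-fold lower. That list call was lost without LP replicate 1 (adjusted p = 0.061) or normal replicate 3 (0.077), after quantile normalization (0.056) and with dim genes left out (0.14; range over all settings 0.0023 to 0.64). Of the 21 mucinous gastric genes 9 rose and 2 fell (median 0.37, camera adjusted p = 0.022, and adjusted p = 0.45 with an estimated correlation). Agr2 was 22.1-fold and Galnt12 8.15-fold higher. The club cell list was not called (adjusted p = 0.46), and the club cell secretoglobin gene Scgb1a1 had a log2 difference of -0.75 ± 0.58 (SE, adjusted p = 0.33). Its SDs were 0.02 in the LP tumours, 0.10 in the normal samples and 1.49 in the Kras tumours, whose spread enters that SE. Scgb1a1 passed the threshold without Kras replicate 3 (adjusted p = 0.041) and with only the 2 groups in the fit (adjusted p = 0.0003, range over all settings 0.0003 to 0.48).

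Of the 24 neutrophil chemokine and cytokine genes 14 rose and 4 fell, or 14 and 5 when adjusted over the list alone (camera adjusted p = 0.0064, and adjusted p = 0.45 with an estimated correlation). Cxcl5 rose 44.2-fold (5.47 ± 0.25 SE, adjusted p = 3.8e-07), Ppbp 40.4-fold (5.34 ± 0.56), Cxcl3 39.9-fold (5.32 ± 0.39) and Il1f9 21.5-fold (4.43 ± 0.26). In the same samples the neutrophil marker list rose, with 6 of 14 genes higher and 1 lower, or 7 and 1 when adjusted over the list alone (median 0.84, and 0.51 without LP replicate 2, camera adjusted p = 0.022, and adjusted p = 0.64 with an estimated correlation). Ltf rose 47.9-fold and S100a8 3.54-fold, while Hdc fell 11.9-fold. Of the 22 interferon response genes 17 rose and 0 fell (camera adjusted p = 6.2e-07, and adjusted p = 0.24 with an estimated correlation). Irf7 was 17.8-fold, Oasl1 16.5-fold and Ifit1 16.2-fold higher. Of the 16 checkpoint ligand genes 5 rose and 2 fell (camera adjusted p = 0.64), among them Vtcn1 (11-fold higher), Ido1 (2.41-fold higher) and Cd200 (4.68-fold lower). Of the 14 MHC class I presentation genes 7 rose and 0 fell (camera adjusted p = 0.024, and adjusted p = 0.45 with an estimated correlation), a call lost without LP replicate 1 (adjusted p = 0.061; range over all settings 0.0032 to 0.45). Of the 9 MHC class II presentation genes 5 fell and 0 rose, or 6 and 1 when adjusted over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.39 with an estimated correlation). Cd74, which is also on the alveolar type 2 list, was 5.17-fold and H2-Aa 4.82-fold lower. Of the 10 genes of B cells, which express MHC class II, 4 fell and 0 rose (camera adjusted p = 0.03, and adjusted p = 0.24 with an estimated correlation), with Jchain 9.29-fold lower. The B cell call was lost without LP replicate 1 (adjusted p = 0.084) and with dim genes left out (0.61, with a median of -0.08 against -0.26; range over all settings 0.00031 to 0.61). In the Kras tumours against normal, 2 B cell genes fell and 0 rose, while 3 MHC class II presentation genes rose and 0 fell. Neither list was called there (camera adjusted p = 0.11 for both). The MHC class II list had medians of -1.21 in the LP and 0.27 in the Kras tumours against normal. The alveolar type 2 list, which shares Cd74 with it, had medians of -4.57 and -0.22. Whether B cells, or a loss of alveolar type 2 cells, contributed to the MHC class II values was not tested.

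Of the 26 mitosis genes 23 rose and 1 fell (camera adjusted p = 3.3e-06, and adjusted p = 0.48 with an estimated correlation), including Mki67 (5.61-fold) and Ccna2 (4.67-fold). Of the 31 DNA replication genes 16 rose and 0 fell, or 21 and 0 when adjusted over the list alone (camera adjusted p = 0.00026, and adjusted p = 0.44 with an estimated correlation). Of the 22 glycolysis and hypoxia genes 15 rose and 3 fell, or 16 and 3 when adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.48 with an estimated correlation). Egln3 was 34.5-fold higher and P4ha1 3.79-fold lower. Of the 21 cholesterol and fatty acid synthesis genes 9 fell and 1 rose (camera adjusted p = 0.0023, and adjusted p = 0.48 with an estimated correlation); the fatty acid desaturase Scd1 fell 9.53-fold and the elongase Elovl6 rose 8.99-fold.

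Of the 15 fibroblast genes 10 fell and 0 rose, or 11 and 0 when adjusted over the list alone (camera adjusted p = 5.4e-06, and adjusted p = 0.24 with an estimated correlation). Pdgfra was 10.6-fold and Dcn 7.01-fold lower. Of the 16 endothelial genes 6 fell and 0 rose, or 7 and 0 when adjusted over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.55 with an estimated correlation), and Pecam1, which encodes CD31, fell 2.30-fold (adjusted p = 0.0033). The leukocyte list, with 4 genes higher and 3 lower of 14, was not called (camera adjusted p = 0.93). Cd52 and Rac2 were 3.14-fold and 3.03-fold higher, and Cytip and Lcp1 6.44-fold and 4.43-fold lower. The macrophage list, with 9 of 17 genes higher and 2 lower, or 9 and 3 when adjusted over the list alone, was not called either (median 0.48, camera adjusted p = 0.081). It was called after quantile normalization (adjusted p = 0.04), without LP replicate 3 (0.045) and in fry (0.034; range over all settings 0.034 to 0.68). Cd68, Cd14 and C1qb rose 2.32-fold, 2.18-fold and 2.08-fold, and Mrc1 fell by 1.44 on the log2 scale. Epcam rose 1.34-fold (adjusted p = 0.019), but not without normal replicate 1 (0.062) or 3 (0.069; range over all settings 0.0078 to 0.069). Ptprc, which encodes CD45, fell 1.59-fold (adjusted p = 0.038), with adjusted p of 0.1, 0.094, 0.066, 0.076 and 0.13 when LP replicates 1 or 3 or normal replicates 1, 2 or 3 were left out, 0.079 after quantile normalization and 0.067 after median centring (range over all settings 0.014 to 0.13). Cxcl1 rose 1.86-fold (adjusted p = 0.018), with adjusted p of 0.072, 0.066 and 0.069 without LP replicate 2, LP replicate 3 or normal replicate 3 (range over all settings 0.0048 to 0.072). Cdkn2a rose 2.46-fold (adjusted p = 0.023), with adjusted p of 0.087 without LP replicate 2 or 3 and 0.051, 0.074 and 0.065 without normal replicates 1, 2 or 3 (range over all settings 0.00026 to 0.087).

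In limma 7931 of 19937 genes (39.8%) were called between LP tumours and normal samples, 4085 higher and 3846 lower, of which 1221 and 1648 changed at least 2-fold. The share of calls that were higher was 51.5%, and over all settings ran from 44.2% with dim genes left out to 61.6% after median centring of the samples. No called gene of the naming rule, and none of 38 gene lists, reversed under either scaling. The values of the groups did not overlap in 55.6% of genes, where chance gives 10%.

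The comparison of Kras tumours with normal epithelium asked the same of adenocarcinoma cells. The ciliated cell gene Rsph4a fell 32.1-fold and the club cell gene Scgb1a1 14.4-fold. The surfactant gene Sftpc stood at 13.84 ± 0.05 against 13.91 ± 0.04 (mean ± SD, n = 3), near the highest value in the table, 14.15, where arrays can saturate. Its log2 difference was -0.06 ± 0.37 (SE, adjusted p = 0.95), and that SE mostly carries the spread of the LP tumours (SD 0.95). The gastric gene Gkn2 rose 43.0-fold, and the sterol pathway gene Sqle fell 7.24-fold. Cd274 had a log2 difference of 0.13 ± 0.34 (SE, adjusted p = 0.87), with SDs of 0.46 in the Kras tumours, 0.07 in the normal samples and 0.74 in the LP tumours.

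Of the 29 ciliated cell genes 27 fell and 0 rose (median log2 difference -2.48, camera adjusted p = 1.7e-38, and adjusted p = 0.12 with an estimated correlation). Rsph4a, a radial spoke gene of motile cilia, fell 32.1-fold (-5.01 ± 0.12 SE, adjusted p = 3e-08) and Sntn 23.4-fold. Spata18 and the axonemal dynein gene Dnah6 fell 29.9-fold and 26.9-fold. Of the 19 club cell genes 12 fell and 0 rose, or 14 and 0 when adjusted over the list alone (camera adjusted p = 2.3e-09, and adjusted p = 0.21 with an estimated correlation). Cyp2b10 fell 40.5-fold (-5.34 ± 0.35, adjusted p = 9.3e-06), Gabrp 15.5-fold and Scgb1a1 14.4-fold (-3.85 ± 0.58, adjusted p = 0.0017). With Kras replicate 3 alone the log2 difference of Scgb1a1 was -2.26 and the median of the club cell list -1.04, against -1.89 over the 3 Kras tumours. Of the 25 alveolar type 2 genes 5 fell and 1 rose, or 7 and 1 when adjusted over the list alone (median -0.22, camera adjusted p = 0.0052, and adjusted p = 0.32 with an estimated correlation), the median being -0.12 with Kras replicate 3 alone, with Lyz1 12-fold lower (-3.58 ± 0.47, adjusted p = 0.00075). Sox2 fell 5.77-fold (-2.53 ± 0.19, adjusted p = 2.4e-05). Inmt, C7, Serping1 and Cftr were also among the largest decreases (55.5-fold, 36.3-fold, 25.1-fold and 23.8-fold).

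Of the 21 mucinous gastric genes 9 rose and 0 fell (median log2 difference 0.14, and 0.24 without normal replicate 1, camera adjusted p = 0.00049, and adjusted p = 0.26 with an estimated correlation). Gkn2, a gastrokine, rose by 5.43 ± 0.45 on the log2 scale (adjusted p = 4e-05), the protease gene Ctse 18.2-fold (adjusted p = 6.9e-07) and the gel-forming mucin gene Muc5ac 4.69-fold. Other large increases were those of Kng2 (34.9-fold), Tdo2 (24.2-fold), St8sia6 (19.6-fold) and Pla2g7 (19.5-fold). Meg3, Mir382 and Dlk1, which lie in the imprinted Dlk1-Dio3 region, rose 23.6-fold (adjusted p = 5.7e-07), 29.3-fold (adjusted p = 3e-08) and 15.4-fold (adjusted p = 0.0058). Of the 36 keratinisation genes 8 rose and 1 fell (camera adjusted p = 0.00085, and adjusted p = 0.39 with an estimated correlation), led by Serpinb5 (32.8-fold) and S100a14 (13.4-fold), whereas Krt5 stood at 7.52 ± 0.42 against 7.46 ± 0.29 and Trp63 at 7.22 ± 0.20 against 7.31 ± 0.14 (mean ± SD, n = 3).

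Of the 21 cholesterol and fatty acid synthesis genes 17 fell and 0 rose, or 18 and 0 when adjusted over the list alone (camera adjusted p = 1.3e-12, and adjusted p = 0.21 with an estimated correlation). The sterol pathway enzymes Sqle and Cyp51 fell 7.24-fold and 4.76-fold. Of the 21 ERK output genes 9 rose and 1 fell, or 10 and 1 when adjusted over the list alone (camera adjusted p = 9.8e-05, and adjusted p = 0.21 with an estimated correlation), with the growth factor gene Ereg 13.2-fold (log2 difference 3.72, and 2.27 with Kras replicate 3 alone) and the phosphatase gene Dusp4 3.05-fold higher. Of the 31 DNA replication genes 18 rose and 0 fell, or 22 and 0 when adjusted over the list alone (camera adjusted p = 3.4e-09, and adjusted p = 0.22 with an estimated correlation), and of the 26 mitosis genes 8 rose and 0 fell, or 12 and 0 when adjusted over the list alone (camera adjusted p = 3.2e-06, and adjusted p = 0.50 with an estimated correlation). The median of the mitosis list was 0.65, was 1.00 without Kras replicate 3, and with Kras replicate 3 alone was 0.11 and not called (adjusted p = 0.22). Of the 22 glycolysis and hypoxia genes 12 rose and 0 fell, or 14 and 1 when adjusted over the list alone (camera adjusted p = 6.8e-05, and adjusted p = 0.39 with an estimated correlation). Of the 19 Wnt pathway genes 8 fell and 0 rose, or 8 and 1 when adjusted over the list alone (camera adjusted p = 0.00055, and adjusted p = 0.39 with an estimated correlation), including the inhibitor gene Wif1 (3.17-fold lower).

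Of the 15 fibroblast genes 8 fell and 0 rose, or 10 and 0 when adjusted over the list alone (median -0.53, and -0.82 without Kras replicate 1, camera adjusted p = 1.7e-06, and adjusted p = 0.26 with an estimated correlation). Dcn was 26.9-fold and Pdgfra 12.7-fold lower, and the small proteoglycan gene Ogn fell 41.7-fold. Of the 9 mesothelial genes 6 fell and 0 rose (camera adjusted p = 9.8e-05, and adjusted p = 0.32 with an estimated correlation). The leukocyte list held 0 called genes of 14 and was not called (camera adjusted p = 0.98), and Ptprc had a log2 difference of -0.27 ± 0.22 (SE, adjusted p = 0.49). Of the 17 macrophage genes 4 rose and 0 fell, or 6 and 0 when adjusted over the list alone (median 0.37, and 0.20 without Kras replicate 2, camera adjusted p = 0.0016, and adjusted p = 0.48 with an estimated correlation), led by Chil3 (3.47-fold). Epcam rose 1.41-fold (adjusted p = 0.018), with adjusted p of 0.07 and 0.075 without normal replicates 1 or 3 and 0.053 and 0.051 without Kras replicates 1 or 2 (range over all settings 0.0056 to 0.26, the highest with Kras replicate 3 alone). Cxcl1 rose 1.97-fold (adjusted p = 0.024), with adjusted p of 0.069, 0.062 and 0.096 without normal replicates 1, 2 or 3 and 0.054 without Kras replicate 2 (range over all settings 0.0059 to 0.096).

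In limma 3408 genes (17.1%) were called between Kras tumours and normal samples, 1436 higher and 1972 lower, of which 439 and 803 changed at least 2-fold. Without normal replicate 3 the count was 2183, and the share of calls that were higher was 42.1%, and over all settings ran from 35.5% at an adjusted p under 0.01 to 53% after median centring. Groups did not overlap in 34.2% of genes, where chance gives 10%. Xist, which is transcribed from the inactive X chromosome of female cells, stood at 11.81 and 12.14 in Kras replicates 1 and 2 and at 5.44 in replicate 3, and lay between 5.31 and 6.60 in the other samples. The Y-linked gene Eif2s3y stood at 4.73 and 4.58 in Kras replicates 1 and 2, at 10.14 in replicate 3, at 7.33 in normal replicate 1 and between 9.10 and 9.72 in the other samples. With the Kras tumours represented by replicate 3 alone, which is then assumed to vary like the other groups, 2825 genes were called.

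**Figure D2:**
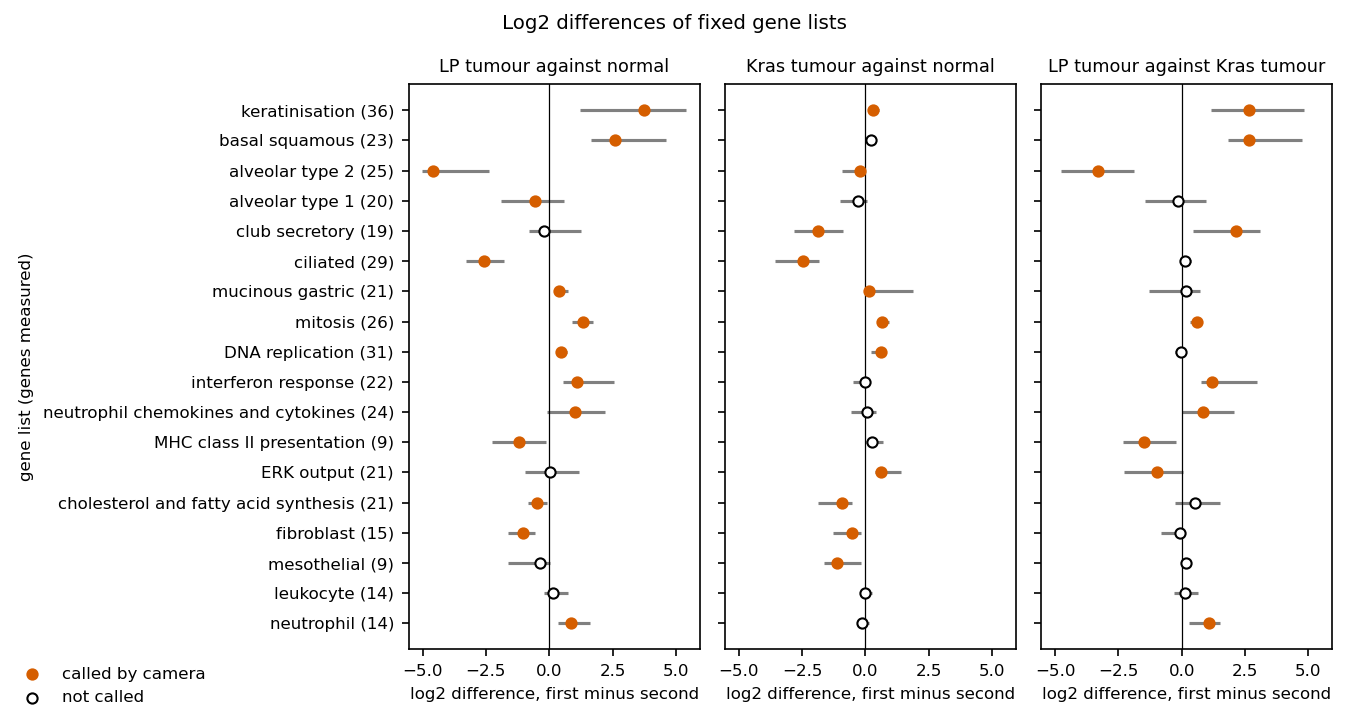
Median log2 difference (horizontal axis, first group minus second) of 18 gene lists in the 3 comparisons; points are medians, bars run between the quartiles of the measured genes, and filled points are lists called by camera at the preset correlation. The alveolar type 2 list lay at -4.57 in LP tumours against normal and at -0.22 in Kras tumours against normal, and the ciliated list at -2.57 and -2.48.

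The direct comparison of the tumour types asked what separates the squamous LP tumours from the Kras adenocarcinomas. Dsg3 was 99.4-fold higher in the LP tumours and Irf7 20.1-fold, and Lamp3 was 94.5-fold lower and H2-DMa 7.98-fold. Cd274 was 5.69-fold higher in the LP tumours (log2 difference 2.51 ± 0.34 SE, n = 3 per group, adjusted p = 0.00054).

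Of the 36 keratinisation genes 34 were higher in the LP tumours and 0 lower (camera adjusted p = 1.3e-22, and adjusted p = 0.068 with an estimated correlation), and of the 23 basal squamous genes 19 were higher and 1 lower, or 19 and 2 when adjusted over the list alone (camera adjusted p = 6.8e-14, and adjusted p = 0.17 with an estimated correlation). Dsg3 was 99.4-fold higher (6.64 ± 0.10 SE), Krt6b 65.6-fold, Krt5 63.9-fold (6.00 ± 0.21) and Trp63 7.44-fold (2.89 ± 0.18, adjusted p = 3.8e-06). Fads2b (145-fold), Serpinb11 (133-fold), Tmprss11g (132-fold), Tmprss11b (110-fold), Clca3b (76.7-fold), Dapl1 (76.6-fold) and Tmprss11a (67.5-fold) were among the largest differences. Of the 19 club cell genes 13 were higher and 2 lower, or 13 and 4 when adjusted over the list alone (camera adjusted p = 0.0026, and adjusted p = 0.50 with an estimated correlation). Gabrp was 64.8-fold and Scgb1a1 8.57-fold higher (3.10 ± 0.58, adjusted p = 0.0033, and 1.51 with Kras replicate 3 alone).

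Of the 22 interferon response genes 17 were higher and 0 lower, or 19 and 0 when adjusted over the list alone (camera adjusted p = 7.8e-10, and adjusted p = 0.17 with an estimated correlation). Irf7 was 20.1-fold and Ifit1 18.7-fold higher. Of the 24 neutrophil chemokine and cytokine genes 11 were higher and 3 lower, or 13 and 3 when adjusted over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.50 with an estimated correlation). Ppbp was 92.9-fold (6.54 ± 0.56 SE, adjusted p = 2.7e-05), Il1f9 38.9-fold, Cxcl5 34.4-fold and Cxcl3 16.8-fold higher. Cxcl1 had a log2 difference of -0.09 ± 0.25 (adjusted p = 0.82). The neutrophil marker list moved with these genes, with 7 of 14 higher and 1 lower, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.71 with an estimated correlation). Of the 26 mitosis genes 8 were higher and 1 lower (camera adjusted p = 0.03, and adjusted p = 0.85 with an estimated correlation), a call lost without LP replicate 1 (adjusted p = 0.14), without Kras replicate 3 (0.15), with sample weights (0.063) and in fry (0.15). The median of that list was 0.60, and 0.43, 0.31 and 0.93 without LP replicate 1, Kras replicate 3 or Kras replicate 2, and 1.23 with Kras replicate 3 alone.

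Of the 25 alveolar type 2 genes 21 were lower in the LP tumours and 2 higher, or 22 and 2 when adjusted over the list alone (median -3.31, camera adjusted p = 1.2e-15, and adjusted p = 0.044 with an estimated correlation). Lamp3 was 94.5-fold lower (-6.56 ± 0.22 SE), Sftpa1 38.6-fold and Sftpc 19.7-fold (-4.30 ± 0.37, adjusted p = 3e-05), and Cldn18 was 34.9-fold lower. Of the 9 MHC class II presentation genes 6 were lower and 0 higher (camera adjusted p = 7.4e-05, and adjusted p = 0.28 with an estimated correlation). H2-DMa was 7.98-fold and Cd74, which is also on the alveolar type 2 list, 5.43-fold lower. Of the 21 ERK output genes 11 were lower and 3 higher (median -0.99, and -0.34 with Kras replicate 3 alone, camera adjusted p = 0.0035, and adjusted p = 0.28 with an estimated correlation), among them Etv5 (17.2-fold), which is also an alveolar type 2 gene, and the feedback inhibitor genes Spry1 (6.77-fold), Spred1 (6.71-fold) and Dusp4 (5.66-fold). Bgn, Bmp4, Gkn2 and Nrn1 were 49.0-fold, 36.1-fold, 37.9-fold and 32.6-fold lower. Of the 16 endothelial genes 5 were lower and 0 higher (median -0.45, camera adjusted p = 0.011, and adjusted p = 0.71 with an estimated correlation), and Pecam1 was 2.23-fold lower (adjusted p = 0.0054). The endothelial call was lost without LP replicate 1 (adjusted p = 0.07), without Kras replicate 1 (0.14, with a median of -0.17), with dim genes left out (0.065) and in fry (0.061; range over all settings 0.00034 to 0.71). The mucinous gastric list was not called (camera adjusted p = 0.89), with Gkn2 and Ctse lower in the LP tumours and Agr2 29.6-fold higher. In limma 5963 genes (29.9%) were called between the tumour types, 2917 higher and 3046 lower in the LP tumours, of which 1076 and 1174 differed at least 2-fold. Groups did not overlap in 42.5% of genes, where chance gives 10%.

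Rsph4a, Inmt, Ogn and Dcn fell in both tumour types, and Serpinb5 rose in both. Of the genes called in both comparisons with normal samples, 663 rose in both, 1434 fell in both and 272 changed in opposite directions, where lists independent of each other would share 294 and 380. The log2 differences correlated across genes at r = 0.468 (Spearman's rho 0.427), where genes are not independent replicates, against 0.499 in simulations of unchanged groups with the same normal samples. The covariance was 0.255 against 0.0149 in the simulations, a difference of 0.24, and the simulations called at most 1 gene in the same direction. No gene changed in the simulated groups, so few calls were bound to occur. That count therefore does not measure how much overlap the shared normal samples add among changed genes. Part of the excess overlap may come from the shared normal samples, which were too few to split. The ciliated list had 27 of 29 genes lower in each tumour type. The fibroblast list had 10 of 15 lower in the LP and 8 in the Kras tumours. For the shared decreases, other cells in the normal samples and a change within epithelial cells were therefore not told apart. Of the 5562 genes called in the LP tumours alone, 3567 also differed between the tumour types, as did 699 of the 1039 called in the Kras tumours alone.

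**Figure D3:**
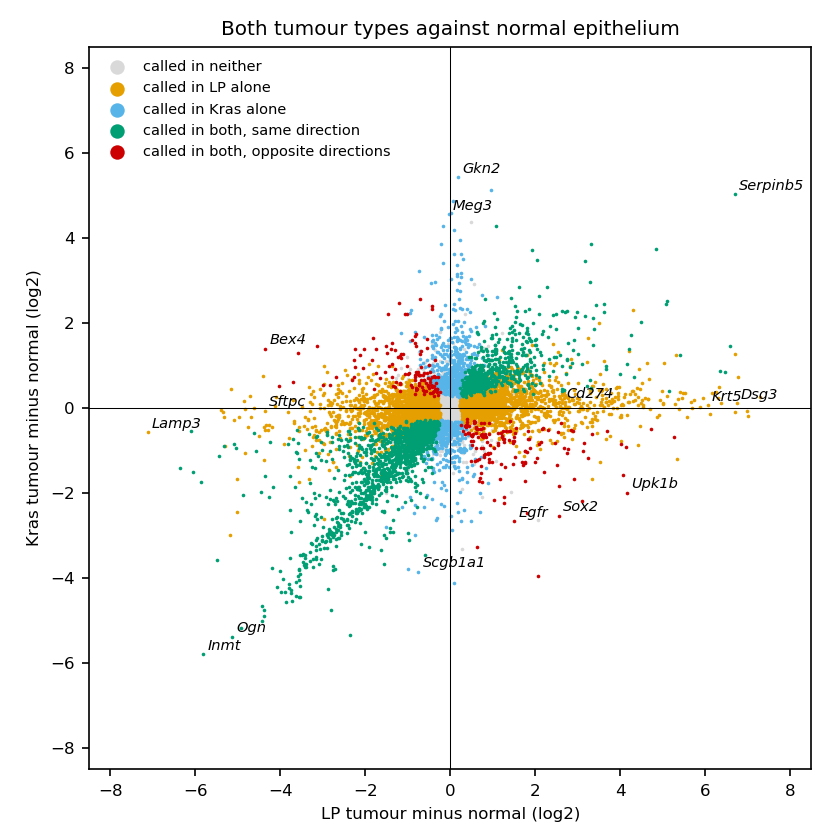
Log2 difference from normal epithelium of each of 19937 genes in LP tumours (horizontal axis) and Kras tumours (vertical axis), coloured by where the gene was called at an adjusted p under 0.05. Dsg3 and Krt5 lay far to the right near 0 on the vertical axis, Gkn2 (0.18 and 5.43) and Meg3 (-0.03 and 4.56) near 0 on the horizontal axis, and Inmt (-5.82 and -5.79) on the shared lower side, while Sox2 (2.55 and -2.53) changed in opposite directions.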

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

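In this part the counts of probe sets without a single gene symbol were chosen after the gene results were seen, and the other splits of the samples were planned. Among the genes of the naming rule and the example genes of the lists, 12 were called in opposite directions in the tumour types against normal epithelium and differed between the tumour types in limma. Sox2, a transcription factor gene of airway and squamous cells, rose by 2.55 in the LP tumours and fell by 2.53 in the Kras tumours on the log2 scale, a difference of 5.08 ± 0.19 (SE, adjusted p = 1.7e-07). The ciliated and club cell lists also fell in the Kras tumours (medians -2.48 and -1.89). A fall there of Sox2, or of the club cell list members Scgb3a1 and Gabrp given below, may therefore reflect the mix of cells. A change within cells was not told apart from it. Upk1b, a uroplakin gene that is also on the mesothelial list, rose by 4.17 in the LP tumours and fell by 1.99 in the Kras tumours, a difference of 6.16 ± 0.33 (adjusted p = 1.4e-06). Bex4 had log2 differences of -4.36 in the LP tumours and 1.40 in the Kras tumours (adjusted p = 0.043), which differed by -5.76 ± 0.40 (adjusted p = 8.1e-06). The call of Bex4 in the Kras tumours was lost, among other settings, without LP replicates 1, 2 or 3 (adjusted p = 0.056, 0.06 and 0.067), normal replicates 1 or 3 (0.14 and 0.15) or Kras replicates 1 or 3 (0.1 each) and with only the 2 groups in the fit (0.091; range over all settings 0.0017 to 0.15), and its value was 2.15 with Kras replicate 3 alone. 1 Kras tumour, at 9.25, lay within the range of Bex4 in the normal samples, 8.53 to 9.36.

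The other 9 genes, with the LP tumours given first, included Scgb3a1 (2.57 and -1.84, a difference of 4.41 ± 0.37 SE), Gabrp (2.07 and -3.95, 6.02 ± 0.24) and Calml3 (5.26 and -0.68, 5.94 ± 0.11). Also among them were Ifit3 (2.52 and -1.35, 3.88 ± 0.34), Wnt7b (1.84 and -0.54, 2.38 ± 0.15), H2-Ab1 (-1.80 and 0.44, -2.25 ± 0.12), Dusp4 (-0.89 and 1.61, -2.50 ± 0.26), Lamb3 (-0.55 and 1.41, -1.96 ± 0.19) and Klf2 (-0.49 and 0.47, -0.96 ± 0.13). Their differences between the tumour types had adjusted p of at most 0.00053. Calls against normal samples were less firm for 6 of them. In the Kras tumours, Ifit3 was not called without normal replicates 2 or 3 (adjusted p = 0.08 and 0.096), with only the 2 groups in the fit (0.06) or with Kras replicate 3 alone (0.12; range over all settings 0.0097 to 0.12). Wnt7b was not called there without normal replicates 1, 2 or 3 (0.1, 0.11 and 0.11) or Kras replicates 1 or 2 (0.069 and 0.1), or with Kras replicate 3 alone (0.32; range 0.0099 to 0.32). H2-Ab1 was not called there, among other settings, without LP replicate 3 (0.056), normal replicates 1 or 3 (0.11 each) or Kras replicates 2 or 3 (0.092 and 0.071), or with Kras replicate 3 alone (0.098; range 0.013 to 0.11). In the LP tumours, Dusp4 was not called without LP replicates 1 or 3 (0.055 and 0.071) or normal replicates 1, 2 or 3 (0.054, 0.076 and 0.054), or after quantile normalization (0.058; range 0.003 to 0.076). Lamb3 was not called there without LP replicates 2 or 3 (0.11, with a value of -0.33, and 0.069), normal replicates 1, 2 or 3 (0.076, 0.11 and 0.13) or Kras replicate 1 (0.053), or after median centring (0.053; range 0.0094 to 0.13). Klf2 was not called in the LP tumours after quantile normalization (0.091) or without normal replicate 3 (0.05; range 0.0053 to 0.091). In the Kras tumours it was not called, among other settings, after quantile normalization (0.062), with a trend and robust prior (0.054), without LP replicate 3 (0.063), normal replicates 1, 2 or 3 (0.083, 0.12 and 0.1) or Kras replicates 1 or 2 (0.098 and 0.073), with only the 2 groups in the fit (0.06) or with Kras replicate 3 alone (0.42, with a value of 0.23; range 0.01 to 0.42). For the 11 genes other than Bex4, the LP tumours and the Kras tumours lay on opposite sides of all normal samples.

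Probe sets that the platform annotation gives several gene symbols or does not list also carried differences. Of 13120 such probe sets, 2976 (22.7%) were called between LP tumours and normal samples, 1160 (8.84%) between Kras tumours and normal samples and 1779 (13.6%) between the tumour types, with limma over all 34760 probe sets. Of the 11799 unlisted ones, 2348, 959 and 1481 were called.

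Other splits of the samples were counted for each number of called genes. For LP tumours against normal samples the real split called 7931 genes and the highest of the other splits 0, for Kras tumours against normal samples 3408 and 0, and for LP against Kras tumours 5963 and 1; in each case 1 of 10 splits, the real one, reached the real count, and 10 splits are too few for a share under 0.05. For the F test over 3 groups, 1 of 100 splits of the 9 samples, the real one, reached the real count of 8660, and the highest of the others was 4170. A share of 1 in 100 is the smallest these splits could give, so chance was unlikely there but not excluded. The splits do not tell in what, besides genotype, the groups differ. No group held more than 3 samples, so single samples were not tested as outliers.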

How the results depend on the processing

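Results were recomputed under up to 23 settings, of which genes on X and Y left out and Kras replicate 3 alone were chosen after the data were seen; an adjusted p under 0.01 was applied to counts of genes only, and the estimated correlation and fry to lists only. For 481 results of genes of the naming rule and example genes of called lists, 9173 recomputed values kept their direction and side of the threshold, 401 lost the call, 15 gained it and 0 reversed. For 38 lists in the 3 comparisons, 2389 kept both, 67 lost the call, 49 gained it and 0 reversed; the estimated correlation accounted for all but 22 of the losses. With an estimated correlation camera called 1 list in LP tumours against normal, 0 in Kras tumours against normal and 1 between the tumour types, in both cases the alveolar type 2 list, against 20, 15 and 12 at the preset correlation. Calls were also lost where the estimated correlation was 0.00, as for the amino acid response list in LP tumours against normal (camera adjusted p = 0.03 at the preset and 0.24 at the estimate). Genes of a list varying together therefore do not account for all the losses. Fry called 21 lists between the tumour types, without comparison to other genes. An adjusted p under 0.01 left 5003, 1873 and 3618 genes in the 3 comparisons. Leaving out each sample in turn gave 2183 to 3752 genes for Kras tumours against normal, the lowest without normal replicate 3, 5833 to 8553 for LP tumours against normal and 4363 to 6762 between the tumour types. With Kras replicate 3 alone the counts were 8589, 2825 and 5102, and without X and Y genes 7702, 3290 and 5785. Same-numbered replicates did not deviate together (r from -0.26 to 0.08 over 9 pairs, 0 of them over 0.1), so the numbers were not read as pairs; with the replicate block the counts were 7025, 2919 and 5361, and 0 lists and 16 of the gene results lost their call and 0 gained one. Among the 16 were Bex4, Klf2 and H2-Ab1 in Kras tumours against normal (adjusted p = 0.086, 0.073 and 0.071). The estimation of sample weights stopped before its convergence tolerance was reached. Signal over background could not be assessed from RMA values, and differences near the lower and the upper end of the scale are compressed.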

Other observations

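The groups of genes in this part other than fixed lists, the Dlk1-Dio3 region among them, were chosen after the results were seen. So were the tests on that region, the fibroblast genes and the inflammatory genes. The comparison with other microRNA genes is an exception, though it was made on a region chosen that way. In the LP tumours against normal, 9 of 18 amino acid response genes rose and 0 fell (camera adjusted p = 0.03, and adjusted p = 0.24 with an estimated correlation), a call lost without normal replicate 1 (adjusted p = 0.075; range over all settings 0.00031 to 0.24). The serine synthesis gene Psat1 rose 7.44-fold and Shmt2 3.48-fold, both higher than in the Kras tumours too (2.88-fold and 2.14-fold), Psat1 by a log2 difference of 1.52, and 0.80 with Kras replicate 3 alone. Of the 24 oxidative phosphorylation genes 10 rose and 1 fell in the LP tumours, or 11 and 1 when adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.48 with an estimated correlation), and 5 rose and 0 fell in the Kras tumours (camera adjusted p = 0.0021, and adjusted p = 0.39 with an estimated correlation). Nkd1, an inhibitor of Wnt signalling, was 10.8-fold lower in the LP than in the Kras tumours. The ligand genes Wnt7b and Wnt4 were 5.19-fold and 4.98-fold higher, but Sfrp1, another inhibitor gene, was higher too. These genes therefore do not give the activity of the pathway. Of the 19 Wnt pathway genes 9 were higher and 1 lower, or 9 and 2 when adjusted over the list alone (camera adjusted p = 0.039, and adjusted p = 0.71 with an estimated correlation). That call was lost without LP replicate 1 (adjusted p = 0.082), Kras replicate 2 (0.14) or Kras replicate 3 (0.078), with sample weights (0.063) and with Kras replicate 3 alone (0.058; range over all settings 0.0069 to 0.71).

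In all, 272 genes were called in opposite directions in the tumour types and differed between them, 146 higher in LP and lower in Kras tumours and 126 the reverse. Among those that changed by at least 1.5 on the log2 scale both ways, chosen after their values were seen, were the receptor gene Egfr (1.51 and -2.67), Enpp3 (4.08 and -1.57), Sptssb (3.11 and -2.19) and Anxa8 (1.80 and -2.46), with LP tumours given first.

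Most genes of the imprinted Dlk1-Dio3 region rose in the Kras tumours: of 47 measured between Dlk1 and Dio3, 36 rose and 0 fell (median log2 difference 1.38), and 37 were higher than in the LP tumours. Over all genes, 1436 of 19937 rose in the Kras tumours. The region was not a fixed list, and the 36 include Meg3, Mir382 and Dlk1, already named among the largest increases. In the LP tumours 0 rose and 1 fell against normal. Of the 47, 40 were microRNA genes, and neighbouring genes are not independent replicates. Dio3 and Rtl1 were not called in the Kras tumours (log2 differences 0.13 and 0.36, limma adjusted p = 0.53 and 0.084). Dlk1 was called, with an SD of 1.90 there. A shift of all microRNA probe sets was excluded, as the 260 microRNA genes elsewhere had a median of 0 (quartiles -0.06 and 0.10). Of the 42 genes of the fibroblast, endothelial and smooth muscle lists, 13 fell and 0 rose (median -0.32), so these lists gave no sign of more such cells than in the normal samples. The normal samples may themselves hold such cells, so carry-over into the Kras samples is not excluded. Without Kras replicate 1 the median of the fibroblast list was -0.82, against -0.53 over the 3 Kras tumours. The sex make-up of the samples stays open: Kras replicate 3, with low Xist, exceeded the normal samples by a median of 1.49, against 1.70 and 0.86 in replicates 1 and 2, but it is a single sample. No biological explanation was tested.

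Of the 15 fibroblast genes 10 fell in the LP tumours and 8 in the Kras tumours, or 11 and 10 when adjusted over the list alone (adjusted p = 0.24 and 0.26 with an estimated correlation). Of the 9 mesothelial genes 6 fell in the Kras tumours (adjusted p = 0.32 with an estimated correlation). In the LP tumours the mesothelial list was not called (camera adjusted p = 0.19), and Upk1b, a member, rose by 4.17. If fibroblasts carried over into the normal samples were the source, the fibrillar collagen genes Col1a1, Col1a2 and Col3a1 would be expected to fall with the other fibroblast genes. Their median log2 difference in the Kras tumours was -0.53, against -1.66 over the 6 other called members, and in the LP tumours -0.49 against -1.63 over 8. The other members were taken because they were called, which makes their medians larger in size. Over all 15 genes of the list the medians were -0.53 in the Kras tumours and -1.04 in the LP tumours. The collagens moved the same way, and carry-over and a difference between epithelial cells cannot be told apart. The gate on EpCAM is meant to remove fibroblasts, but how completely it did so was not assessed here.

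Genes of inflammation higher in the LP tumours were Cd274, the cytokine genes Il1a (10.8-fold, log2 difference 3.43 ± 0.41 SE) and Tnf (2.70 ± 0.26), and the chemokine gene Cxcl5. Carry-over of leukocytes stays open. Ptprc had a log2 difference of -0.67 (95% interval -1.17 to -0.17), and its call was lost in 7 settings, with values from -0.72 to -0.51 in those and from -0.84 to -0.51 over all settings. It is a single gene, and other leukocyte genes went both ways, with Cd52 (1.65) and Rac2 (1.60) higher and Cytip (-2.69) and Lcp1 (-2.15) lower. Macrophage carry-over stays open: 9 of 17 macrophage genes rose and 2 fell, or 9 and 3 when adjusted over the list alone, and the list had a median of 0.48, with an excess in LP replicates 1, 2 and 3 of 0.36, 0.73 and 0.34. Neutrophil carry-over stays open too: the neutrophil list had a median of 0.84, and its excess in LP replicates 1, 2 and 3 was 0.20, 1.52 and 0.83, beside 1.82, 3.27 and 2.81 for Cd274 and 2.45, 4.12 and 3.73 for Il1a. Cxcl5 was 4.96, 5.6 and 5.84 above the normal samples in the same replicates. Of the neutrophil list, Ltf, S100a8 and S100a9, at means of 13.62, 8.21 and 8.77 in the LP tumours, are also made by epithelia. Il1a, Tnf and chemokines are also made by macrophages. The gate is meant to remove CD45-positive cells, but how completely it did so was not assessed here. With 3 samples, too few to test whether these values vary together, leukocytes and tumour cells as sources cannot be told apart.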
